A study of Mus musculus with 3 samples.

How the data were processed

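Total RNA of RAW264.7 cells was biotin-labelled with a whole-transcript sense target assay and hybridised to Affymetrix arrays, per the labels' protocols. Each of 3 cultures had received 500 µM oleate, elaidate or palmitate for 6 hours, and each gave 1 array. Groups were taken from the labels' statement of the fatty acid, and all arrays were mapped to a group. The deposited values are log2 expression values, 1 per probe set, made with RMA per the submitters' processing notes; the version of RMA is not given in the sources used here. RMA is a method that corrects background, makes the distributions of arrays alike and summarises the probes of a probe set by median polish. The values were used as deposited. They ran from 0.81 to 13.67 on the oleate array, 0.94 to 13.62 on the elaidate array and 0.98 to 13.60 on the palmitate array. Arrays have no depth to report, and the number of arrays limits the precision.

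Probe sets were named through the platform annotation supplied with the series, which can be old. Of the 35556 probe sets, 21218 had 1 gene symbol, 1881 had several and 12457 were not named there. Only the first kind was used for genes. Of these, 21185 matched a gene of the mouse RefSeq annotation by its gene identifier, and 1 symbol of a fixed list was updated to its present form. For 1386 genes with several probe sets the mean of the probe sets was taken, and 17434 genes had 1 probe set. The filter kept genes whose mean over the 3 arrays was at or above the median of all 18820 genes, a log2 value of 4.14, which left 9410 genes. No coordinates are given, because the files name no genome build. Genes of the fixed lists without a probe set of their own were not analysed here.

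With 1 array per fatty acid no test of the treatments was possible. Differences of log2 values were computed for elaidate minus oleate, palmitate minus oleate and palmitate minus elaidate, and genes at least 2-fold different were counted. The genes named in the text are the 12 with the highest and the 12 with the lowest difference in each comparison, leaving out symbols of predicted genes, microRNA genes, small nucleolar RNA genes and olfactory or vomeronasal receptor genes by how they begin or end, together with Angptl4, Plin2, Cd36 and Cpt1a. For the gene lists described, every member at least 2-fold different was named, or otherwise the 2 to 4 members furthest from 0. For some list results that did not stand apart or had no percentile, fewer members or none were named. Small RNA genes under other symbols, such as Scarna13, were not left out. A few more members (Hspa5, Tnf and Il1b) and genes already named in another comparison were added after their values were seen. Similarity of the arrays was described by the standard deviation of the differences and by the array that held the middle value. Values were called equal when they differed by at most 1e-06.

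The 31 gene lists covered lipid metabolism, stress responses, inflammation, cell cycle, organelles, macrophage identity and markers of other cell types. For each list the median difference over members past the filter was set against 10000 random lists of the same size, drawn from 20 bins of mean expression. A list stands apart when its percentile is at or below 2.5 or at or above 97.5. This describes the arrays and does not test the fatty acids. The interval given beside a median is the exact binomial order-statistic 95% interval over the genes of the list. Lists with fewer than 5 members past the filter received values only. The lists, the rule for named genes, the filter and all alternatives except those said to be added later were chosen before the data were examined.

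Alternatives were no filter, a filter on the highest of the 3 values, a filter at the 75th percentile, limits of 1.5-fold and 3-fold, centring of each array on its median, cyclic loess between the arrays with limma 3.58.1 in R 4.3.3 (span 0.7, 3 iterations), the probe set with the highest mean, counts without the symbols that the rule for named genes leaves out, list means, unmatched random lists, and lists without the member furthest from 0. Lists and array similarity without genes equal on all 3 arrays were added after seeing the data. Overlaps of comparisons that share an array were set beside those of independent lists; without replicate arrays, chance overlap through the shared array could not be simulated at the error of expressed genes. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

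The counting and list steps were tested on simulated data for palmitate minus oleate over 9410 genes. Of simulated genes, 0% with a true 1.5-fold difference, 52.0% with a 2-fold and 100% with a 3-fold or 4-fold difference passed the 2-fold limit, and 0 unchanged genes did. The simulated noise was a chosen value far below the 2-fold limit, because no replicate arrays exist to measure it. This result therefore gives no rate of false differences for the deposited arrays. Of simulated lists of 20 genes, 5.5% stood apart without a shift and 100% with a log2 shift of 0.2. Genes of these simulated lists varied independently, with a spread chosen below that of palmitate minus oleate. The shift moved every member, equal ones included. These shares therefore give no error rate or power for the deposited lists. Signals of probe sets with several genes or none were left out of the gene counts because they cannot be given to 1 gene.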

Results

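RAW264.7 cells, a mouse macrophage line, were exposed for 6 hours to 500 µM of a single fatty acid bound to serum albumin at 2 fatty acid molecules per albumin, and their RNA was profiled on whole-transcript expression arrays. The series holds 3 arrays, 1 for each of 3 fatty acids: oleate, a cis monounsaturated fatty acid; elaidate, its trans isomer of the same chain length; and palmitate, a shorter saturated fatty acid. The question set by the design is how the response of a macrophage line to a trans fatty acid compares with that to a cis and to a saturated one at the same dose and time. There are no replicate arrays and no array of untreated cells. Each difference below is therefore between a pair of arrays, has no replicate check and no p-value, and says nothing of a response relative to no fatty acid. Median log2 values over the 35556 probe sets were 3.57 on the oleate array, 3.58 on the elaidate array and 3.61 on the palmitate array. Of 18820 genes with their own probe set, 9410 passed the filter on low values and enter the counts, those of gene lists included.

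The palmitate array stood away from the other 2, which were close to each other. The standard deviation of the log2 differences over the 9410 genes was 0.13 for elaidate minus oleate, 0.38 for palmitate minus oleate and 0.33 for palmitate minus elaidate. At least 2-fold differences were found for 10 genes between elaidate and oleate, all 10 higher on the elaidate array. Palmitate against oleate gave 155 genes higher and 115 lower, and palmitate against elaidate gave 92 higher and 82 lower. Among the 4186 genes with 3 different values, elaidate held the middle one for 60.2%, oleate for 32.3% and palmitate for 7.53%. Arrays that differ by equal noise alone would hold it equally often, but palmitate stood away, so that is no baseline for elaidate. With palmitate away, elaidate and oleate would hold the middle value equally often if only equal noise separated them. As a gauge of differences between arrays without expression, 1157 olfactory and vomeronasal receptor genes had standard deviations of 0.093, 0.093 and 0.092 in the same 3 comparisons, and at most 1 of them passed 2-fold in any comparison. The largest receptor gene difference was 1.48 in size, for elaidate minus oleate, beside a highest value of 1.41 among genes past the filter. Equal values on both arrays held for 75.7%, 74.5% and 76.5% of the receptor genes, which narrows their spread. Receptor genes sit at a median log2 value of 2.22, so they do not stand in for replicate error of expressed genes. Equal values on both arrays, to within 1e-06, occurred for 44.1%, 32.3% and 34.2% of the genes past the filter.

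**Figure D1:**
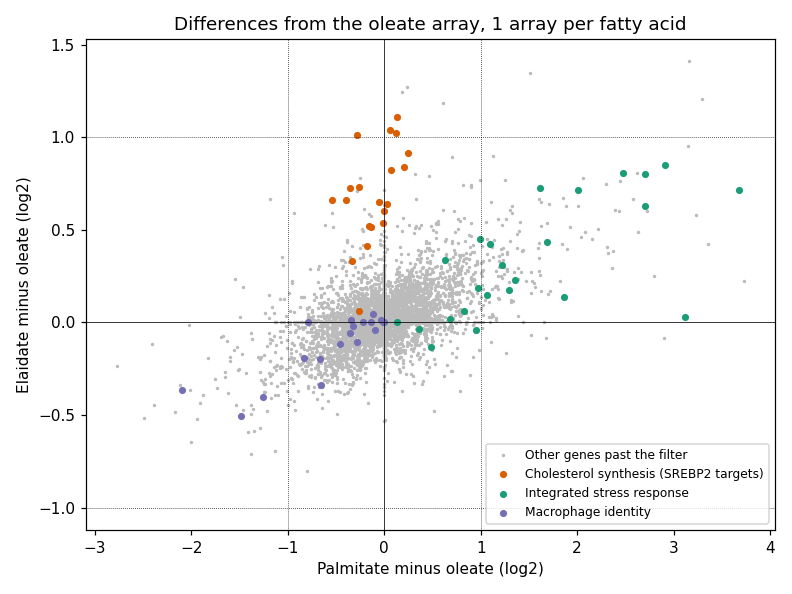
Each point is a gene past the filter, with palmitate minus oleate (log2) on the horizontal axis and elaidate minus oleate (log2) on the vertical axis, 1 array per fatty acid; dotted lines mark 2-fold. The 20 cholesterol synthesis genes (orange) lie above 0 on the vertical axis, the 24 integrated stress response genes (green) lie to the right of 0, and 18 of the 19 macrophage identity genes (purple) lie to the left of 0.

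The trans isomer was compared with the cis one first. Genes of cholesterol synthesis and uptake were higher on the elaidate than on the oleate array, together with genes of fatty acid synthesis. All 20 measured cholesterol genes, targets of the transcription factor SREBP2, were higher, with a median log2 difference of 0.66 (95% interval over genes 0.54 to 0.84), or 1.58-fold. The 4 past 2-fold were Pmvk at 1.11, Insig1, which retains the SREBP complex in the endoplasmic reticulum, at 1.04, the lanosterol synthase gene Lss at 1.03 and the mevalonate decarboxylase gene Mvd at 1.01. Cyp51, a sterol demethylase, followed at 0.91. Of 15 fatty acid synthesis genes, targets of SREBP1, 12 were higher, 1 was lower and 2 were equal, with a median of 0.44 (0.14 to 0.61). Lpin1, a phosphatidate phosphatase, at 1.27 and Acss2, which makes acetyl-CoA from acetate, at 1.24 were past 2-fold. Both lists lay at percentile 100 among random lists matched on expression, which describes these arrays only.

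Other genes past 2-fold on the elaidate array relative to oleate were Plk2, a polo-like kinase, at 1.41, the small Cajal body RNA gene Scarna13 at 1.35, the neutral amino acid transporter Slc1a4 at 1.21 and the retinol dehydrogenase gene Rdh11 at 1.19. Rgs1, a regulator of G protein signalling, differed by 0.95. No gene was 2-fold lower. The named genes with the lowest differences were the pseudokinase gene Trib1 at -0.71, the scavenger receptor Marco at -0.69 and Tgfbi at -0.65, followed by Soga1 and Dok3 at -0.59 each. Rnf145 stood at -0.57, the collagenase Mmp13 at -0.53, Nfam1 at -0.52, Trem1 and the complement gene C1qa at -0.51 each, and the transcription factor Irf8 and Mettl23 at -0.50 each. Of the 24 integrated stress response genes past the filter (27 were measured), targets of ATF4 and CHOP, 20 were higher, 3 lower and 1 equal on the elaidate array. Their median was 0.27 (0.06 to 0.63) and none passed 2-fold; Nupr1 at 0.85, Chac1 at 0.81 and Cth at 0.80 were the highest. Among 18 type I interferon response genes 15 were higher and 3 equal, with a median of 0.20 (0.03 to 0.37), led by Ifit1 at 0.90, Rsad2 at 0.75 and Cxcl10 at 0.63. Both lists stood apart at percentile 100.

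Smaller medians also stood apart between elaidate and oleate, where random matched lists had medians near 0. Of 19 macrophage identity genes 11 were lower, 4 higher and 4 equal, with a median of -0.04 (-0.20 to 0) at percentile 0.020, led by C1qa at -0.51 and C1qc at -0.40. DNA replication genes had a median of -0.06 (-0.14 to 0.01) at percentile 0.040, with Mcm7 at -0.27 and Tk1 at -0.17 lowest. Phospholipid synthesis genes had a median of 0.03 (0 to 0.14) at percentile 99.5, with Lpin1 past 2-fold. The NRF2 antioxidant genes had a median of -0.01 (-0.07 to 0.04) at percentile 1.61, with Me1 at 0.52 and Hmox1 at -0.24, and their mean was at percentile 16.5. The immediate early genes had a median of -0.03 (-0.17 to 0.09) at percentile 0.26, with Fos at -0.31 and Myc at -0.21, and lay at percentile 47.4 without the member furthest from 0. The osteoclast markers had a median of -0.06 (-0.29 to 0.52) at percentile 1.25 over 6 genes, with Dcstamp at 0.52 and Tnfrsf11a at -0.29, and lay at percentile 49.95 without the filter; their mean was on the other side of 0, at 0.01.

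**Figure D2:**
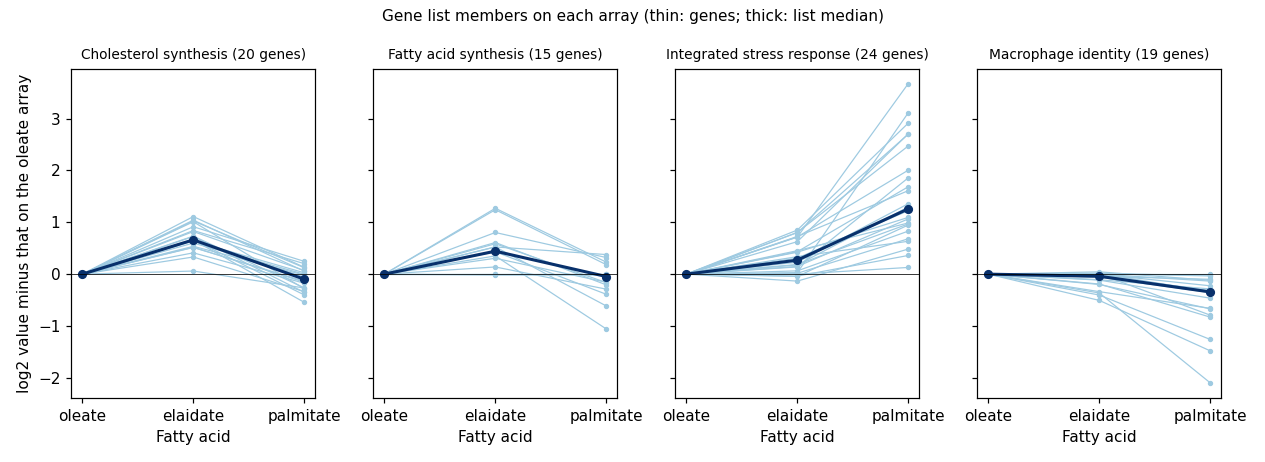
Members of 4 gene lists on the 3 arrays, as the log2 value minus that on the oleate array (vertical axis) for each fatty acid (horizontal axis); thin lines are genes and thick lines list medians. The median of the cholesterol synthesis genes was 0.66 above oleate on the elaidate array and -0.10 on the palmitate array, while that of the integrated stress response genes was 0.27 and 1.26.

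The saturated fatty acid was then compared with the cis monounsaturated one. On the palmitate array, genes of the integrated stress response were higher than on the oleate array, as were most genes of the NF-kB and interferon lists, and genes of macrophage identity, DNA replication and oxidative phosphorylation were lower. All 24 integrated stress response genes were higher, 15 of them at least 2-fold, with a median log2 difference of 1.26 (0.95 to 2.01), or 2.40-fold. The highest were the pseudokinase gene Trib3 at 3.68, Ppp1r15a, a phosphatase subunit that reverses stress-induced translation arrest, at 3.12, and Nupr1 at 2.91. Sesn2 differed by 2.71, Cth, an enzyme of cysteine synthesis, by 2.70, Chac1, which degrades glutathione, by 2.47 and Gpt2 by 2.01. The cystine transporter Slc7a11 stood at 1.86, Aldh18a1 at 1.69, Atf4 itself at 1.61, the amino acid transporter Slc7a5 at 1.36 and Atf3 at 1.30. Nars at 1.22, the asparagine synthetase gene Asns at 1.10 and Cebpg at 1.07 completed the 15. The list lay at percentile 100.

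Among the 21 NF-kB inflammatory genes 14 were higher, 5 lower and 2 equal on the palmitate array relative to oleate, with a median of 0.46 (0 to 0.79). The neutrophil chemokine Cxcl2 at 2.90, Ptgs2, the inducible prostaglandin synthase, at 1.71, the chemokines Ccl5 at 1.40 and Ccl4 at 1.26, and Traf1 at 1.10 were past 2-fold. Cytokine genes of the list went both ways, with Il1b lower at -0.67 and Tnf higher at 0.33. Of 18 interferon response genes 15 were higher and 3 equal, with a median of 0.57 (0.02 to 0.91), and Rsad2 at 2.29, Cxcl10 at 1.88, Ifit1 at 1.12 and Mx2 at 1.01 were past 2-fold. Both lists lay at percentile 100. The endoplasmic reticulum chaperone list also stood apart, at percentile 98.5, but with a small median of 0.04 (0 to 0.38); 15 of its 23 genes were higher, 5 equal and 3 lower. Its members past 2-fold were the co-chaperone Dnajb9 at 2.00 and Herpud1, of endoplasmic reticulum degradation, at 1.39, while the main chaperone Hspa5 stood at 0.38. The immediate early genes had a median of 0.12 (-0.25 to 0.58) at percentile 99.7, which was 50.8 without the filter. They went both ways, with the phosphatase gene Dusp1 at 1.68, Atf3 at 1.30 and Fos at -1.28.

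Lower on the palmitate than on the oleate array were 18 of 19 macrophage identity genes, with the remaining one equal and a median of -0.34 (-0.79 to -0.12). Mertk, a receptor for apoptotic cells, at -2.10 and the complement genes C1qa at -1.48 and C1qc at -1.26 were past 2-fold. Of markers of other cells, the 2 fibroblast markers past the filter, Col1a1 and Acta2, were equal on all 3 arrays, the only adipocyte or hepatocyte marker past it, Alb, stood at -0.16, and none of the lymphocyte markers passed it. Of the dendritic cell markers, Batf3 stood at -0.15 and Ccr7 was equal. The 6 osteoclast markers went both ways, from Tnfrsf11a at -0.90 to Clcn7 at 0.68, with a median of -0.10 (-0.90 to 0.68) at percentile 10.8. DNA replication genes were lower for 16 of 18 members and equal for 2, with a median of -0.43 (-0.66 to -0.33). Ccne1, the cyclin of the entry into S phase, at -1.56 and the ribonucleotide reductase subunit gene Rrm2 at -1.14 were past 2-fold. Oxidative phosphorylation genes were lower for 23 of 25 members and equal for 2, with a small median of -0.18 (-0.25 to -0.08). No member of that list passed 1.5-fold, and Sdhd at -0.44 and Ndufa4 at -0.41 were the furthest from 0. Percentiles were 0 for macrophage identity and DNA replication and 0.040 for oxidative phosphorylation.

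Genes of lipid handling went in different directions between palmitate and oleate. The list of fatty acid uptake and scavenger receptors had a median of -0.28 (-0.65 to 0.32) at percentile 0.030, with 9 of 14 members lower and Marco at -1.14 past 2-fold. Phospholipid synthesis genes had a median of -0.07 (-0.32 to 0) at percentile 1.53, with the acyltransferase genes Mboat1 at -1.47 and Lpcat1 at -1.07 past 2-fold, and lay at percentile 5.69 without Mboat1. The cholesterol synthesis genes had a median of -0.10 (-0.27 to 0.06) at percentile 2.90 and did not stand apart, with 13 lower and 7 higher. Hmgcs1 at -0.54 and Stard4 at -0.40 were the furthest from 0, and without the filter the percentile was 2.01. For the fatty acid synthesis genes the median was -0.05 (-0.29 to 0.18) at percentile 11.6, with the fatty acid synthase gene Fasn at -1.06. The PPAR target genes had a median of 0 (-0.33 to 0.17), yet Acot2, an acyl-CoA thioesterase, stood at 2.15 and Cpt1a, the carnitine palmitoyltransferase that controls fatty acid entry into mitochondria, at -1.60. Cpt1a was also the member of the fatty acid oxidation list past 2-fold. The sterol exporter Abcg1 stood at 1.34 among LXR targets with a median of 0. The ceramide synthases Cers6 at -1.21 and Cers4 at -1.20 were past 2-fold in the sphingolipid list, whose median was -0.03 (-0.26 to 0.01) at percentile 10.5. Glycolysis and HIF1 target genes had a median of -0.11 (-0.25 to 0.13) at percentile 0.69, with the oxidoreductase gene Ero1a at 1.22, and their mean lay at percentile 36.0.

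Among all genes, the named genes with the highest values on the palmitate relative to the oleate array also included the orphan receptor gene Gprc5a at 3.72, the stress-inducible growth arrest gene Gadd45a at 3.36 and Slc1a4 at 3.29. The macrophage growth factor gene Csf1 stood at 3.23, Plk2 at 3.16, Rgs1 at 3.15, Ndrg1 at 2.80 and the alcohol dehydrogenase gene Adh7 at 2.72. The lowest were the fractalkine receptor gene Cx3cr1 at -2.77, the myeloid receptor gene Trem1 at -2.49, Tlr8, an endosomal sensor of RNA, at -2.41 and the immune checkpoint gene Vsir at -2.38. Tifab stood at -2.17, Asb2 at -2.12, the Notch-modifying glycosyltransferase gene Lfng at -2.02 and Tgfbi at -2.00, followed by Nfam1 at -1.94, Nbeal2 at -1.91 and the D-type cyclin gene Ccnd3 at -1.88. In the list of p53 targets, with a median of 0 (-0.33 to 0.52), Gadd45a, Plk2 and Mdm2 at 1.39 were past 2-fold. The autophagy adaptor gene Sqstm1 at 1.55 and Slc7a11 were past 2-fold in the NRF2 list, whose median of 0.03 (0 to 0.25) lay at percentile 96.9.

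**Figure D3:**
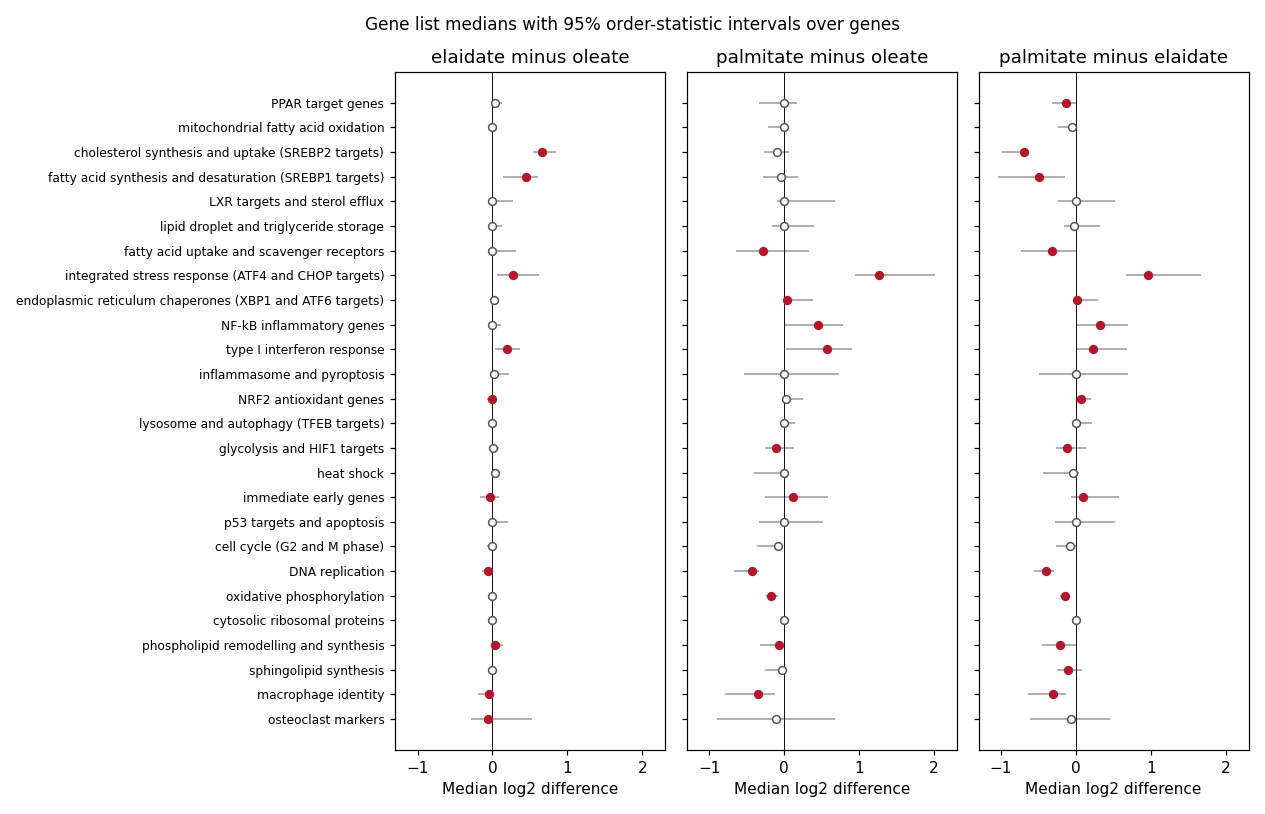
Median log2 difference (horizontal axis) of each of the 26 gene lists with at least 5 members past the filter in the 3 comparisons, with 95% order-statistic intervals over genes, which are not replicate error; filled points stood apart from random matched lists. The integrated stress response was highest in both palmitate comparisons, and the cholesterol synthesis genes were highest in elaidate minus oleate (0.66) and lowest in palmitate minus elaidate (-0.69).

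The saturated and the trans fatty acid were compared last. On the palmitate array, genes of the integrated stress response were higher than on the elaidate array, as were the medians of the NF-kB and interferon lists, and lower were genes of sterol and fatty acid synthesis. All 24 integrated stress response genes were higher, 11 of them at least 2-fold, with a median of 0.95 (0.67 to 1.67). Ppp1r15a at 3.09, Trib3 at 2.96, Sesn2 at 2.08 and Nupr1 at 2.06 led the list, and the others past 2-fold were Cth at 1.90, Slc7a11 at 1.72, Chac1 at 1.67, Gpt2 at 1.29, Aldh18a1 at 1.25, Slc7a5 at 1.13 and Atf3 at 1.12. All 20 cholesterol synthesis genes were lower, with a median of -0.69 (-0.99 to -0.64). Mvd at -1.29, the synthase gene Hmgcs1 at -1.20, the isomerase gene Idi1 at -1.08 and the sterol carrier Stard4 at -1.07 were past 2-fold. Of the fatty acid synthesis genes 12 of 15 were lower and 3 equal, with a median of -0.49 (-1.04 to -0.15), and Fasn at -1.41, Aacs at -1.14, Acss2 at -1.06 and Lpin1 at -1.04 were past 2-fold. These 3 lists lay at percentiles 100, 0 and 0.

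In the NF-kB list 14 of 21 genes were higher on the palmitate than on the elaidate array, 4 lower and 3 equal, with a median of 0.32 (0 to 0.70) at percentile 100, with Cxcl2 at 2.99, Ptgs2 at 1.54 and Traf1 at 1.10 past 2-fold. In the interferon list 12 of 18 were higher, 1 lower and 5 equal, with a median of 0.23 (0 to 0.68) at percentile 100.0, and Rsad2 at 1.55 and Cxcl10 at 1.25 were past 2-fold. The immediate early genes, at a median of 0.10 (-0.07 to 0.57), and the NRF2 genes, at 0.07 (0.00 to 0.20), stood apart at percentiles 99.8 and 99.8. Their members past 2-fold were Dusp1 at 1.77 and Atf3, and Slc7a11 and Sqstm1 at 1.34. Without the member furthest from 0 the immediate early genes lay at percentile 55.9. The chaperone list, at a median of 0.01 (0 to 0.29) and percentile 97.9, lay at 95.6 without Dnajb9, which stood at 1.38, beside Herpud1 at 1.35.

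Macrophage identity genes were lower on the palmitate than on the elaidate array for 18 of 19 members and equal for 1, with a median of -0.30 (-0.64 to -0.13) and Mertk at -1.74 past 2-fold. DNA replication genes were lower for 15 of 18, with a median of -0.41 (-0.57 to -0.30), Ccne1 at -1.41 and Rrm2 at -1.19. Oxidative phosphorylation genes had a median of -0.14 (-0.21 to -0.08), with Sdhd at -0.56 and Ndufa4 at -0.48. The list of uptake and scavenger receptors had a median of -0.31 (-0.73 to 0), with Scarb1, the receptor for high-density lipoprotein, at -0.98 and the lipase gene Lpl at -0.89. Percentiles were 0.0050, 0, 0.33 and 0.020. Phospholipid synthesis genes stood at -0.21 (-0.46 to 0), percentile 0.020, with Mboat1 at -1.31 and Lpin1 past 2-fold. For 3 more lists with small medians the result depended on a setting. The PPAR targets, at -0.13 (-0.33 to 0) and percentile 1.76 with Acot2 at 1.70 and Cpt1a at -1.39, had a mean at percentile 29.3. The glycolysis genes, at -0.11 (-0.27 to 0.13) and percentile 0.80 with Pdk1 at -0.98 and Ero1a at 0.98, had a mean at percentile 34.6. The sphingolipid genes, at -0.10 (-0.26 to 0.08) and percentile 2.07 with Cers4 at -1.35 and Cers6 at -1.09, lay at 6.14 without Cers4. The fatty acid oxidation genes, at -0.06 (-0.24 to 0) and percentile 7.57, did not stand apart. Neither did the osteoclast markers, at -0.06 (-0.61 to 0.46) and percentile 18.9, with Tnfrsf11a at -0.61 and Clcn7 at 0.46.

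Named genes with the highest values on the palmitate relative to the elaidate array included Gprc5a at 3.50, Gadd45a at 2.93, Csf1 at 2.65, Ndrg1 at 2.55, Rgs1 at 2.20, Tent5c at 2.15, Adh7 at 2.12 and Slc1a4 at 2.08. The lowest were Cx3cr1 at -2.54, Tlr8 at -2.29, Trem1 at -1.98, Vsir at -1.94 and the ribonuclease gene Rnase6 at -1.85. Asb2 and Ptger4, a receptor for prostaglandin E, stood at -1.78 each, Tifab at -1.68, Lfng and the leukotriene receptor gene Cysltr1 at -1.66 each, and the D-type cyclin gene Ccnd1 at -1.64. The sterol exporters Abca1 at 1.17 and Abcg1 at 1.07 were past 2-fold, while the LXR list had a median of 0 (-0.24 to 0.52). In the p53 list, with a median of 0 (-0.27 to 0.52), Gadd45a, Plk2 at 1.75 and Mdm2 at 1.15 were higher and Sesn1 at -1.04 was lower.

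Set side by side at the matched dose and time, the palmitate array differed at least 2-fold from both others in the same direction for 88 genes higher and 66 lower, since 88 of the 92 and 66 of the 82 genes past 2-fold against elaidate were also past it against oleate. Independent lists of these sizes would share 1.52 and 1.00 genes. Both comparisons use the palmitate array, and the elaidate and oleate arrays differed little (standard deviation of differences 0.13). A large overlap follows from this, so independent lists are no fair baseline. The elaidate array was at least 2-fold higher than both others for 3 genes, Acss2, Lpin1 and Mvd, and lower for 0; with each array centred on its median Mvd lay just short of 2-fold and the count was 2. The oleate array was lower than both others for 3, Plk2, Scarna13 and Slc1a4, and higher for 0. Of the lists with a median of 0 between elaidate and oleate, some had narrow and some wide intervals over genes. Among the narrow ones, oxidative phosphorylation genes had a median of 0 (-0.01 to 0.00), fatty acid oxidation genes a median of 0 (0 to 0.03) and NF-kB genes a median of 0 (-0.02 to 0.11). Wider ones belonged to the LXR targets (0 to 0.27), the uptake and scavenger receptors (-0.06 to 0.31) and the p53 targets (-0.02 to 0.20). These intervals cover the spread between genes, the 44.1% of equal values narrow them, and equality of the treatments was not tested.

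Of 4 genes tied to lipid handling that were named in advance, Cpt1a differed most. It stood at -0.21 for elaidate minus oleate, -1.60 for palmitate minus oleate and -1.39 for palmitate minus elaidate. Angptl4, the lipoprotein lipase inhibitor that is deleted in the mice named in the series title, stood at -0.08, -0.33 and -0.25 in the same comparisons. Plin2, a lipid droplet coat protein, stood at 0.20, 0.17 and -0.03, the last of which turned above 0 when each array was centred on its median. Cd36, a fatty acid receptor, did not pass the filter: it held 2.27 on all 3 arrays, near the median of 2.22 of the olfactory and vomeronasal receptor genes, so its equal values do not compare the fatty acids. The lipid droplet list of 10 genes had medians of 0 (0 to 0.13), 0 (-0.16 to 0.40) and -0.03 (-0.16 to 0.32), with Hilpda at 0.85 for palmitate minus oleate the furthest from 0. None of the 3 results of this list stood apart.

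Several other lists did not stand apart in any comparison. Cytosolic ribosomal protein genes had medians of -0.00, -0.00 and 0, with Rpl14 at -0.37 and Rpl4 at 0.13 the furthest from 0 for elaidate and for palmitate minus oleate. Heat shock genes had medians of 0.03, 0 and -0.03, with Dnajb1 at -0.70 for palmitate minus oleate. Lysosome and autophagy genes had medians of 0 in all 3 comparisons, with Sqstm1 past 2-fold in both palmitate comparisons. Inflammasome genes had medians of 0.02, 0 and 0, with Casp4, the caspase that senses lipopolysaccharide, at 1.29 for palmitate minus oleate and 1.07 for palmitate minus elaidate. The mitotic cell cycle genes had medians of 0, -0.08 and -0.09, with Aurkb at -0.67 for palmitate minus oleate. In that comparison 13 of 16 were lower, 1 higher and 2 equal, with an interval of -0.36 to -0.01 at percentile 4.64. For palmitate minus elaidate 12 were lower, 2 higher and 2 equal, at percentile 5.01. Of the alternative activation genes 4 passed the filter, with Klf4 at 0.46 for palmitate minus oleate, too few for a percentile. In all, 37 of the 78 list results with a percentile stood apart, where 3.9 would for lists of unrelated genes. Genes of a list can move together between any pair of cultures, so 3.9 is not the count without a fatty acid effect. The lists share genes and the comparisons share arrays, so these results are not independent.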

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

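These signals came from probe sets that the gene comparisons do not use, and no test of them was chosen before the result was seen. Among the 854 probe sets past the filter that are assigned to several genes, 12 were at least 2-fold higher and 8 at least 2-fold lower on the palmitate than on the oleate array, up to a log2 difference of 4.52 and down to -1.75. That highest difference exceeds the 3.72 of Gprc5a, the highest among genes with their own probe set, but the probe set cannot be given to 1 gene. Among the 3764 probe sets past the filter with no gene in the annotation used, 164 were at least 2-fold higher and 84 lower, against 56 higher and 64 lower for elaidate minus oleate. The 9410 genes past the filter gave 10 higher and 0 lower for elaidate minus oleate, so 2-fold differences were more frequent among these unnamed probe sets. No replicate array gives a background for these counts, and no explanation of them was tested.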

How the results depend on the processing

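All alternatives except the removal of genes equal on all 3 arrays were planned; that removal was chosen after seeing the data. No list stood apart on the opposite side under the alternatives run. Among lists that stood apart, the osteoclast markers in elaidate minus oleate changed sign, from a median of -0.06 to a mean of 0.01. Some lists that did not stand apart, with medians near 0, also changed sign, such as the lipid droplet genes in palmitate minus elaidate, from a median of -0.03 to a mean of 0.05. Among named genes, Plin2 in palmitate minus elaidate turned above 0 under centring. Of the 78 list results, 71 kept their call without the filter, 77 with cyclic loess, 78 with centring, 64 with list means, 72 with unmatched random lists, 72 without the member furthest from 0 and 71 without equal genes. Of 84 named-gene results, Mvd in elaidate minus oleate moved below 2-fold, to 0.99 under centring, which shifted the median of all genes by -0.02, 0.02 and 0.04 in the 3 comparisons. Cyclic loess moved no named gene by more than 0.0004, so it tests little here. Counts followed the limit by construction. At 1.5-fold, higher and lower counts were 68 and 6 for elaidate minus oleate, 430 and 445 for palmitate minus oleate, and 299 and 417 for palmitate minus elaidate. At 3-fold they were 0 higher for elaidate minus oleate, 57 and 24, and 33 and 15. With the filter at the 75th percentile, which tests fewer genes, they were 95 and 62 for palmitate minus oleate and 53 and 43 for palmitate minus elaidate. At 1.5-fold against both other arrays, oleate was higher for 6 and lower for 39 genes, elaidate higher for 26, and palmitate higher for 278 and lower for 327. Without the filter, elaidate held the middle value for 58.3% and palmitate for 9.29% of genes. Percentiles of lists that gained or lost their call follow. The cause of these changes was not tested. With list means, lost calls were PPAR targets, palmitate minus elaidate, at 29.3, NRF2, elaidate minus oleate, at 16.5, glycolysis, palmitate minus oleate and minus elaidate, at 36.0 and 34.6, phospholipids, palmitate minus oleate, at 2.54, sphingolipids, palmitate minus elaidate, at 3.22, and, with its sign turned, osteoclast markers, elaidate minus oleate, at 48.6. Gained calls were NRF2, palmitate minus oleate, at 99.7, lysosome, palmitate minus oleate and minus elaidate, at 97.7 and 98.2, p53 targets at 99.8, 100.0 and 99.6 in the 3 comparisons, and ribosomal proteins, elaidate minus oleate, at 1.5. With unmatched lists, gained calls were PPAR targets, chaperones and ribosomal proteins in elaidate minus oleate at 98.2, 99.4 and 0.55, and SREBP2 targets, NRF2 and the mitotic cycle in palmitate minus oleate at 0.85, 98.4 and 1.75. Without the filter, SREBP2 targets, palmitate minus oleate, gained a call at 2.01. Lost calls there were chaperones, glycolysis and sphingolipids in palmitate minus elaidate at 97.3, 2.77 and 2.90, immediate early genes in both palmitate comparisons at 50.8 and 51.1, and osteoclast markers, elaidate minus oleate, at 49.95. Without the member furthest from 0, chaperones, glycolysis, immediate early genes and sphingolipids in palmitate minus elaidate lay at 95.6, 4.06, 55.9 and 6.14. Immediate early genes in elaidate minus oleate then lay at 47.4, and phospholipids in palmitate minus oleate at 5.69. Removal of other members was not run, so these calls were not shown to rest on the member left out. Cyclic loess left chaperones, palmitate minus elaidate, at 97.4. Without equal genes, lost calls were PPAR targets and sphingolipids in palmitate minus elaidate at 5.08 and 3.74, NRF2 in elaidate minus oleate at 4.67, and glycolysis and phospholipids in palmitate minus oleate at 4.61 and 6.58; gained calls were LXR targets in elaidate minus oleate at 99.6 and inflammasome genes in palmitate minus oleate at 98.0. No paired analysis was possible because each fatty acid has 1 array. Signal near background limits the genes below the filter, which were not counted.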

Other observations

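The tests of the aminoacyl-tRNA synthetases were fixed before their result was seen, except that Cars had already been noticed among the genes higher on the palmitate array and was left out. The integrated stress response list, which holds cytosolic synthetase genes, was also higher on that array, Nars included. The synthetase result therefore cannot count as a blind prediction. All other tests in this part were chosen after the result was seen.

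Aminoacyl-tRNA synthetases, the enzymes that load amino acids onto tRNAs, were not covered by a list of their own. Of 15 cytosolic synthetase genes outside the fixed lists, 12 passed the filter, and 7 of them were higher, 1 lower and 4 equal on the palmitate relative to the oleate array. Their median log2 difference was 0.80 (95% interval over genes 0 to 0.89), with Tars highest at 1.00. For palmitate minus elaidate the median was 0.62 (0 to 0.68), and for elaidate minus oleate it was 0.14 (0 to 0.23), at percentile 100.0. The 16 mitochondrial synthetase genes past the filter had a median of 0 (-0.02 to 0.18) for palmitate minus oleate, with Wars2 highest at 0.35. The hypothesis was that the cytosolic enzymes, several of which are known ATF4 targets, move with the integrated stress response and the mitochondrial ones do not. For palmitate minus oleate the cytosolic set lay at percentile 100 among random matched lists and the mitochondrial set at 55.9, which is consistent with it for these arrays.

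Elaidate held the middle of the 3 values for 60.2% of genes with 3 different values. Among the 92 genes at least 2-fold higher on palmitate than on elaidate, elaidate minus oleate had a median of 0.27 (0.22 to 0.40). If genes were chosen without the oleate array, noise of a shared oleate array would give 0 or less. The difference that chose these genes leaves that array out, but the filter on the mean of 3 arrays uses it, as the RMA summary can. For the 82 lower genes the median was -0.0727 (-0.13 to 0), which leaves that noise open. Palmitate RNA mixed into the elaidate sample would, without noise, give the same implied share for genes higher and lower on palmitate. The shares were 13.4% (11.7 to 15.6) and 25.2% (19.2 to 29.2), with a gap of 3.56 percentage points between the intervals. These genes were chosen by palmitate minus oleate, and the shares use the oleate array again. Noise of that array could shift the shares unequally, so the gap cannot exclude mixing. With 1 array per fatty acid, a difference between culture wells cannot be told apart from an effect of the fatty acid. A graded response to the fatty acids stays open and untested.

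The SREBP2 targets were highest on the elaidate array for 20 of 20 members, whereas a mixture of oleate and palmitate RNA would lie between the other arrays. A shift between arrays that depends on intensity would move other genes at the same expression levels alike. The highest median among 10000 random lists of such genes was 0.1244, below the list's median of 0.66 (0.54 to 0.84). The list's percentile of 100 among random matched lists had already fixed that order, so this is no separate test. A difference between culture wells, such as cell density or medium, was not tested for this list and stays open, as does an effect of the trans fatty acid on sterol regulation.

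Exactly equal values on all 3 arrays occurred for 53.1% of the 23099 named probe sets. They were more frequent among probe sets of olfactory and vomeronasal receptor genes, at 67.8% (65.0 to 70.4), than among probe sets of genes past the filter, at 30.3% (29.5 to 31.2), a gap of 37.4 percentage points. Median polish over so few arrays, as RMA uses, is a candidate explanation. Simulated probe sets with noise alone were equal in 16.2% of cases with 10 probes and 76.9% with 25. These shares lie below and above both observed ones, and the probe numbers of the real probe sets were not used. The simulation therefore cannot decide on this explanation. A floor on low values would pile the equal values onto a few low values. The commonest held 1.24% of the equal probe sets, and the equal values ran from 1.36 to 13.55. The criterion written first, over 50% sharing a value with another probe set, was met at 77.6%. It was replaced after this was seen because repeated values occur across the range. With so many equal values, many list medians lie at or near 0.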
